A study of Mus musculus with 12 samples.

How the data were processed

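Small RNAs from 12 libraries of CD1 mouse embryonic gonads were measured by sequencing on a MiSeq instrument. The libraries cover primordial germ cells (PGCs) and gonadal somatic cells (SC) of female and male embryos on embryonic days 11.5 (E11.5), 12.5 (E12.5) and 13.5 (E13.5), with 1 library for each of the 12 combinations. Per the labels' protocols, the mesonephros was removed after sexing by PCR, and groups of about 80 gonads were separated with anti-CD15 paramagnetic beads on a magnetic column. The same protocols give a PGC enrichment of 93 to 96% by a PGC-specific stain and a somatic purity of over 90%, and RNA shorter than 100 bp was used.

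Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trim Galore, aligned with Bowtie 1.1.2 to GRCm38 and normalized with DESeq. The step that counted reads per microRNA, the annotation release and the features behind the size factors are not given in the sources used here. The deposited values are a normalized signal, made by the authors as counts per mature microRNA divided by 1 size factor per library. All 616 listed microRNAs were read, and the values of the single-library files differed by 0 from the table of all samples. Of the deposited values, 100% were 0 or a whole multiple, at a tolerance of 1e-06, of a step equal to the smallest value divided by 5, and no value stood for 1 to 4 reads. Whole reads and size factors were therefore taken back from the values, and a value of 0 is read as under 5 reads; 1797 of the 7392 values are 0.

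Each library's precision depends on its microRNA reads, which ran from 166804 to 1768825. A share of reads carries an exact Clopper-Pearson interval at 95% confidence. The floor of 5 reads per library corresponds to 2.83 to 29.98 reads per 1e+06 microRNA reads (RPM). Such intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

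Libraries were grouped by the labels. The labels describe both cell fractions as coming from gonads of the same stage and sex, so PGC and SC libraries were compared as 6 stage-by-sex pairs; the labels do not say that both fractions came from the same pool of gonads. Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1 (moderated test, empirical Bayes with trend), on the 513 microRNAs with a mean normalized count of at least 5. An adjusted p under 0.05 (Benjamini-Hochberg) was the threshold for a call. The comparison of cell types had the pair as a block, with 5 residual degrees of freedom. Sex and stage were additive terms within each cell type in 1 fit of all 12 libraries, with 4 residual degrees of freedom, and the change of the sex difference over time was a slope per embryonic day. In all, 9 comparisons were tested. With 1 library per condition the p-values measure only the spread between these libraries and not that between repeated isolations. The empirical Bayes step pools this spread over microRNAs, so a p-value can be far smaller than 4 residual degrees of freedom alone would allow. Female and male libraries of a single stage were compared as values without a test.

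All comparisons were also computed after bringing each library to the same total of microRNA reads (RPM); these results are given as values at equal totals beside those on the deposited scale.

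The comparisons, the 24 microRNA lists and the rule for naming microRNAs were fixed before the data were examined. Named microRNAs passed the threshold, had a mean normalized count of at least 50 and the same direction in every matched pair, and were among the 10 with the largest log2 change in each direction. Where fewer than 3 passed in a direction, the 3 with the smallest unadjusted p are named as not past the threshold. At single stages the 5 largest differences in each direction were taken among microRNAs with a value of at least 100 in either library, and those at least 4-fold apart were counted. Up to 4 members of each list with the highest mean, miR-202 and miR-140 in SC, and miR-290 cluster members in PGCs were added. The lists hold clusters (miR-290 to miR-295, here the miR-290 cluster, miR-302 with miR-367, here the miR-302 cluster, miR-17/92 with its paralogues, miR-199a/214, miR-143/145, miR-182 with miR-183 and miR-96, here the miR-182 cluster, X-linked Fx-mir, the X-linked miR-322 with miR-503 and miR-221 with miR-222, here the miR-322 and miR-221 clusters, the imprinted Dlk1-Dio3 and Sfmbt2 clusters), families (let-7, miR-125/99/100, miR-200, miR-29, miR-30, miR-181, miR-34/449, Hox-cluster miR-10/196), gonadal sex-differentiation microRNAs, and microRNAs abundant in other cell types (erythroid, endothelial, muscle, neural, and kidney or epithelial). Members were matched by the microRNA's own name and arm.

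The 22 lists with at least 3 tested members were compared with all other microRNAs by camera in limma with a preset correlation of 0.01, adjusted over all 198 tests of list and comparison together. Camera with an estimated correlation and fry were run beside it. Members of a cluster share a transcript and are not independent, so list members were also counted by the test of single microRNAs, once adjusted over all tested microRNAs and once over the list alone. Where a microRNA was at 0 in both libraries of a stage, its change is given as a lower bound against the floor of 5 reads in each of these libraries, since its fitted change depends on the added 1. Where 1 of these libraries was at 0, the fitted change is given and depends on the added 1 too. The difference in stage change was also fitted with values of 0 raised to that floor.

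Hairpin positions come from the RefSeq annotation of GRCm38.p6, in which 84 of 86 looked-up hairpin names were found. Several microRNAs hold identical values in all libraries, such as miR-465b-3p and miR-465c-3p, and miR-199a-3p values are 1.9999 to 2.0027 times those of miR-199b-3p, so reads were shared between copies in a way not given in the sources used here. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

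The procedure was tested on simulated data with the depths of these libraries, in which 200 microRNAs were changed in each of 5 runs. With the true scaling, 2-fold, 4-fold and 16-fold changes between cell types were called in 63.3%, 94.9% and 98.8% of cases, and 5.56% of unchanged microRNAs were called. For sex in PGCs these shares were 26.0%, 80.9% and 91.2%, with 1.53% false calls, and for stage in PGCs 20.0%, 72.8% and 91.2%, with 2.17%. A call in the wrong direction occurred 0 times. These shares hold for a known scaling, which the real libraries lack, and for a dispersion of 0.0975 estimated from values at equal totals. They do not give the power or the false-call share on the deposited scale. With each simulated library brought to its own total, as at equal totals, 92.6%, 26.6% and 20.6% of unchanged microRNAs were called, since the changed ones move the total. Alternatives covered the added constant, the filter, the scaling, the trend, the block, the libraries used, and each library left out in turn. Recomputed size factors, limma voom on the recovered reads, the raising of 0 to the floor, the list tests at equal totals and the omission of doubted libraries were chosen after seeing the data. The microRNAs under the filter were left out of the tests because most of their values are 0. Small RNAs other than microRNAs are not analysed here.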

Results

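Small RNAs were sequenced from primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, and from the somatic cells (SC) of the same kind of gonad, in female and male CD1 mouse embryos on 3 days around the onset of sex differentiation, E11.5, E12.5 and E13.5. There was 1 library for each of the 12 combinations, 6 per cell type, and no replicate of any combination. Each value is a normalized count of a mature microRNA as the authors deposited it. In PGCs, the microRNA reads numbered 1221211 (female) and 432830 (male) at E11.5, 166804 and 184174 at E12.5, and 430262 and 392261 at E13.5. In SC they numbered 1768825 and 611229 at E11.5, 1492596 and 1380552 at E12.5, and 1693396 and 1038570 at E13.5. Of the 616 microRNAs listed, 350 (PGC female E12.5) to 543 (SC female E13.5) were detected, 285 in all 12 libraries, and the 10 most abundant took 35.5 to 51.0% of the reads of a library.

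The sum of the deposited counts differed more between libraries than the reads did. It ran from 105730 in PGC female E12.5 to 2158040 in SC female E11.5, a ratio of 20.4, against 10.6 for the reads. Sum and reads rose together (Pearson r = 0.977, permutation p = 2e-05; Spearman rho = 0.916, permutation p = 0.00012; 12 libraries, log2 scale, 1e+05 resamples, two-sided, the one relation across libraries that was tested). Each sum is the reads divided by a size factor that varied less than the reads, so this relation was largely set in advance. Its p-values are not evidence about the factors. Without both E12.5 PGC libraries, the farthest from the median, r was 0.948. Within PGCs r was 0.984 and within SC 0.847, over 6 libraries each. The deposited size factors were 1.08 to 1.58 in PGCs and 0.614 to 1.15 in SC. They did not rise with the reads (Spearman rho = -0.517 between factor and reads, without a test). Every comparison of cell types is therefore given on the deposited scale and at equal totals, as reads per 1e+06 microRNA reads (RPM). Equal totals moved the median log2 difference of all 513 tested microRNAs between PGCs and SC from -2.57 to -0.74.

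**Figure D1:**
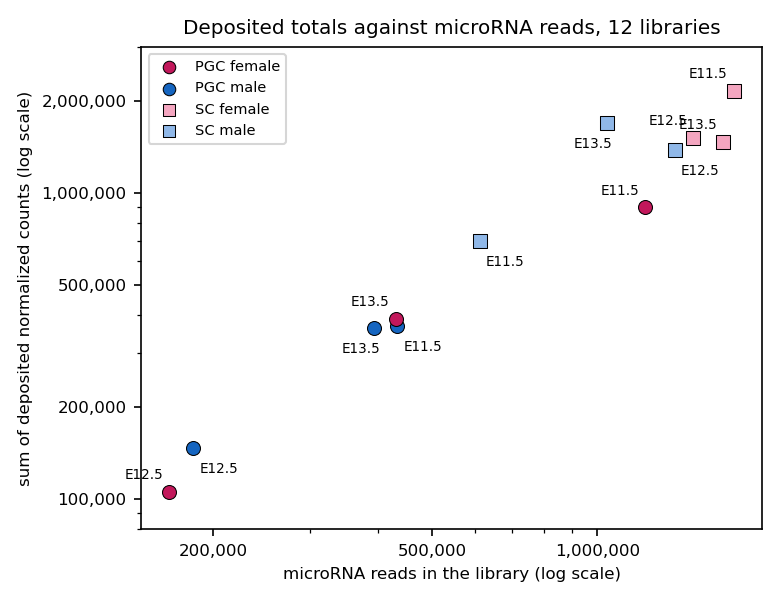
Sum of deposited normalized counts (vertical, log scale) against microRNA reads (horizontal, log scale) for each of the 12 libraries. The sums run from 105730 to 2158040, with PGC female E12.5 lowest and SC female E11.5 highest.

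PGCs were compared with SC to find the microRNAs that mark each cell type. The miR-290 cluster, abundant in embryonic stem cells and early embryos (chromosome 7, 3218626 to 3220841, 9 hairpins), was higher in PGCs for all 13 tested members, on both scales and also adjusted over the list alone. At equal totals 11 members passed without both E12.5 PGC libraries and 7 without both E13.5 SC libraries (13 each on the deposited scale), with all 13 still positive. The cluster took 9.36% ± 5.12 of reads in PGCs and 0.189% ± 0.242 in SC (SD, n = 6 each). Its most abundant member, miR-292a-5p, averaged 35459 ± 23322 RPM in PGCs against 517 ± 744 RPM in SC (SD, n = 6), a fitted difference of 20.3-fold on the deposited scale and 95.4-fold at equal totals. The largest difference was that of miR-291a-5p, with a log2 change of 5.51 ± 0.79 (SE, adjusted p = 0.000200, 6 of 6 pairs; 7.62 at equal totals). miR-291a-5p and miR-290a-5p were at 0 in both E11.5 SC libraries, so their sizes, and the ranking by size, depend on the added 1. miR-290a-5p (4.96), miR-291b-5p (4.66), miR-292a-3p (3.95), miR-294-3p (3.82), miR-291a-3p (3.67), miR-295-3p (3.34) and miR-293-3p (3.08) were higher in 6 of 6 pairs too. In SC the cluster's share was 0.0244 to 0.0619% at E11.5 and E12.5, and 0.366% (female; 95% interval 0.357 to 0.375) and 0.604% (male; 0.589 to 0.619) at E13.5. PGC female E11.5 held 0.235% (0.226 to 0.244), against 7.13% (7.05 to 7.21) in PGC male E11.5.

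The X-linked Fx-mir cluster, whose microRNAs are abundant in testis (chromosome X, 66776757 to 68010179, 21 hairpins), was also higher in PGCs. Of its 26 tested members, 17 passed as higher and 1 as lower (16 and 1 adjusted over the list alone), with 18 and 1 at equal totals. The lower one, miR-547-3p (log2 -3.43, 4 of 6 pairs), was named after its values were seen. miR-741-3p was 7.53-fold higher (log2 2.91 ± 0.73, SE, adjusted p = 0.0015; 6 of 6 pairs), and 32.3-fold at equal totals. It was at 0 in both E11.5 SC libraries, so these sizes depend on the added 1. The cluster took 1.25% ± 1.54 of reads in PGCs and 0.104% ± 0.155 in SC (SD, n = 6), and in SC male E11.5 all its members were at 0, that is under 5 reads each. Without both E12.5 PGC libraries 2 members passed as higher on each scale, and without both E13.5 SC libraries 7 passed on the deposited scale and 0 at equal totals. The miR-182 cluster, known from sensory organs (chromosome 6, 30165918 to 30169737), passed as higher for 3 of 4 members on the deposited scale (0 adjusted over the list alone) and for 4 of 4 at equal totals. miR-182-5p averaged 26191 ± 15391 RPM in PGCs and 1748 ± 679 RPM in SC (SD, n = 6; log2 1.44 ± 0.61, SE, adjusted p = 0.0345, 5 of 6 pairs; 3.67 at equal totals, 6 of 6 pairs). For the epithelial miR-200 family, 1 of 7 members passed as higher on the deposited scale (0 adjusted over the list alone) and 6 at equal totals. miR-200b-3p was 7.53-fold higher at equal totals, in 6 of 6 pairs. Without both E13.5 SC libraries 0 members of the miR-182 cluster and of the miR-200 family passed on either scale.

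**Figure D2:**
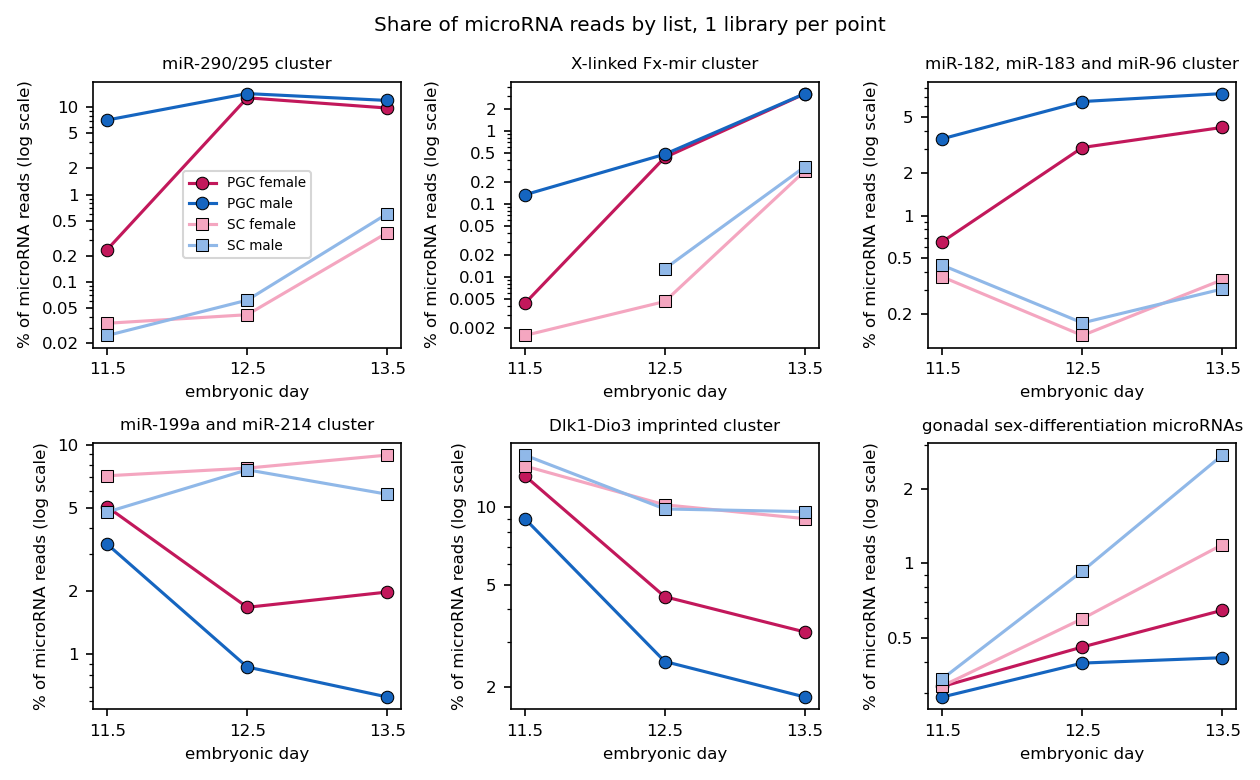
Percent of microRNA reads (log scale) taken by 6 microRNA lists against embryonic day, 1 library per point, with PGCs as circles and SC as squares; the Fx-mir cluster in SC male E11.5, at 0 reads, is not drawn. In PGC female E11.5 the miR-290 cluster share is 0.235%, against 7.13% in PGC male E11.5.

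MicroRNAs of mesenchymal and smooth muscle cells were higher in SC. All 6 tested members of the miR-199a/214 cluster and all 4 of miR-143/145 were lower in PGCs on both scales, also adjusted over each list alone. miR-143-3p averaged 36841 ± 13094 RPM in SC and 16150 ± 17303 RPM in PGCs (SD, n = 6), 17.5-fold lower in PGCs on the deposited scale (log2 -4.13 ± 0.71, SE, adjusted p = 0.000227; 6 of 6 pairs) and 3.73-fold at equal totals. miR-199a-3p was 16.5-fold lower, and 3.51-fold at equal totals. The imprinted Dlk1-Dio3 cluster, expressed from the maternal chromosome (chromosome 12, 109544541 to 109747960, 56 hairpins), was lower in PGCs for 82 of 82 members on the deposited scale and for 57 at equal totals (82 and 70 adjusted over the list alone). Its share was 5.72% ± 4.47 in PGCs and 11.5% ± 2.91 in SC (SD, n = 6). miR-127-3p had a log2 change of -3.57 ± 0.64 (SE, adjusted p = 0.000227; 6 of 6 pairs) and -1.34 at equal totals. The largest decreases by the naming rule were those of miR-1a-3p (-5.07), miR-666-5p (-4.76), miR-370-5p (-4.73), miR-136-3p (-4.67), miR-214-5p (-4.56), miR-199b-5p (-4.56), miR-1197-3p (-4.54), miR-3099-3p (-4.54), miR-145a-3p (-4.54) and miR-3081-3p (-4.49). miR-202-5p, a microRNA of gonadal somatic cells taken as a check of the labels, was lower in PGCs (log2 -4.03 ± 0.80, SE, adjusted p = 0.000296; 6 of 6 pairs; -1.81 at equal totals, 4 of 6 pairs), and miR-140-3p had -2.91 and -0.68. Without both E12.5 PGC libraries 0 members of the 3 lists passed at equal totals, against 77, 6 and 4 on the deposited scale, and the same 0 was found without both E13.5 SC libraries.

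For several broad families the result depended on the scale. All 15 tested members of the let-7 family, which rises as cells differentiate, were lower in PGCs on the deposited scale (median log2 -2.57), against 2 at equal totals (-0.55; 0 adjusted over the list alone). In the cell-cycle cluster miR-17/92 and its paralogues, 15 of 21 members were lower and 2 higher on the deposited scale, while at equal totals 6 were higher and 0 lower. miR-92a-3p had a log2 change of -0.92 (adjusted p = 0.129, 6 of 6 pairs lower) and 1.32 at equal totals (adjusted p = 0.0126, 6 of 6 pairs higher). Of 11 miR-30 members, 8 were lower and 0 higher on the deposited scale, and 0 lower and 3 higher at equal totals. Of 3 miR-302 cluster members, 2 were lower and 0 higher, and 0 lower and 1 higher at equal totals. For miR-125/99/100, 10 of 10 members were lower and 6 of 10 at equal totals, as were 8 and 3 of 8 for miR-181, 4 and 2 of 4 for miR-34/449, 15 and 8 of 15 for the miR-322 and miR-221 clusters, and 9 and 2 of 9 for Hox-cluster miR-10/196. In the Sfmbt2 cluster 9 of 24 were lower and at equal totals 2 higher. The gonadal list had 9 of 10 lower, and 1 higher and 3 lower at equal totals. The single tested miR-29 member, miR-29a-3p, had log2 changes of 0.27 (not past) and 2.45 (higher). Among the lists of other cell types, lower members on the deposited scale and at equal totals were 8 and 1 of 10 (erythroid), 2 and 1 of 2 (endothelial), 3 and 1 of 4 (muscle), 4 and 1 of 10 (neural, with 3 higher at equal totals) and 2 and 0 of 5 (kidney or epithelial, with 3 higher).

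By limma, 36 microRNAs were higher and 396 lower in PGCs on the deposited scale, so that 91.7% of the 432 calls were lower. At equal totals 69 were higher and 131 lower, 65.5% of 200, and 36 and 131 passed in the same direction on both scales. By quantile normalization 78 were higher and 102 lower, and by voom on the recovered reads 77 higher and 56 lower. At equal totals the 200 calls became 94 or 86 without PGC female or male E12.5, 119 or 103 without the PGC E13.5 libraries, 92 or 85 without the SC E12.5 libraries and 121 or 100 without the SC E13.5 libraries (female or male), 17 without both E12.5 PGC libraries and 7 without both E13.5 SC libraries. With the pair as a block, each library left out also took its partner out of the estimate. These counts therefore show the dependence on whole stage-by-sex pairs and not on 1 cell type's library. Camera with the preset correlation placed the miR-290 cluster (adjusted p = 2e-34), Fx-mir (4.6e-29), the miR-182 cluster (0.000125) and miR-200 (0.000126) higher, and Dlk1-Dio3 (1.5e-07) lower, than other microRNAs. With an estimated correlation the adjusted p was 0.292, 0.274, 0.968, 0.968 and 0.968, so these calls did not hold. Across all comparisons 45 of 198 list tests were called with the preset correlation and 0 with the estimated one or with fry.

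**Figure D3:**
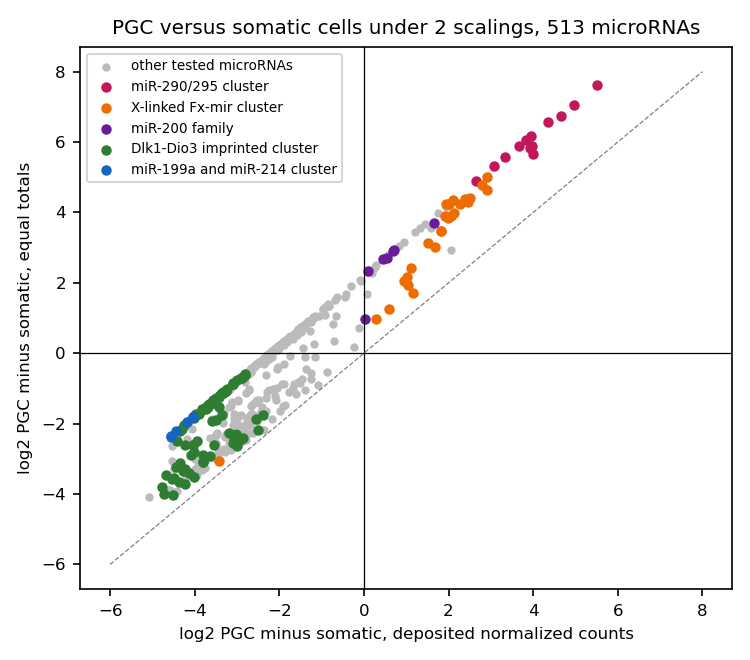
Log2 difference between PGCs and SC on the deposited scale (horizontal) and at equal totals (vertical), 1 point per tested microRNA (513), with 5 lists coloured and the dashed line marking equal values. miR-290 cluster members are positive on both axes, Dlk1-Dio3 and miR-199a/214 members negative on both.

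The change from E11.5 to E13.5 in the PGC libraries spans the days on which germ cells take a female or male course. The Fx-mir cluster rose: 25 of 26 members passed on both scales and adjusted over the list alone, with a median log2 change of 6.12, or 5.65 with 8 members that were at 0 in both libraries of a stage set to their bound. miR-465c-5p had the largest rise (log2 7.68 ± 1.05, SE, adjusted p = 1.5e-07; 2 of 2 sexes; 338-fold and adjusted p = 0.00663 at equal totals), followed by miR-465b-5p (7.40), miR-871-3p (6.74), miR-465a-5p (6.65), miR-880-3p (6.60), miR-883a-3p (6.52), miR-871-5p (6.48), miR-743a-3p (6.16), miR-743b-3p (6.12) and miR-470-5p (6.04). With 53 reads of the whole cluster in PGC female E11.5 and a floor of 5 reads, some of these microRNAs were at 0 there. Their sizes depend on the added 1. The cluster went from 0.00434% (female) and 0.133% (male) of reads at E11.5 to 3.22% and 3.24% at E13.5. miR-202-5p rose in both sexes (log2 2.48 ± 0.84, SE, adjusted p = 0.0179; 3.10 at equal totals). Of the miR-290 cluster, 11 of 13 members rose on the deposited scale, among them miR-292a-5p (2.38; adjusted p = 0.022) and miR-293-3p (2.81; adjusted p = 0.00819), and 0 at equal totals, where 11 passed adjusted over the list alone (13 on the deposited scale). Its share went from 0.235% to 9.78% of reads in females and from 7.13% to 11.9% in males, so the rise rests mostly on PGC female E11.5. At equal totals miR-182-5p (1.84; adjusted p = 0.0154) and 2 other miR-182 cluster members rose, against 0 of 4 on the deposited scale.

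The Dlk1-Dio3, miR-199a/214 and miR-143/145 clusters fell in PGCs over the same days, as did the miR-302 cluster, whose difference between cell types depended on the scale. In the Dlk1-Dio3 cluster 68 of 82 members fell, and 60 at equal totals (71 and 67 adjusted over the list alone; median log2 -3.02, or -2.83 with 18 members at their bound). miR-758-3p had a log2 change of -6.14 ± 0.87 (SE; 2 of 2 sexes; -6.27 at equal totals). All 6 members of miR-199a/214 (5 at equal totals), all 4 of miR-143/145 on both scales and all 3 of the miR-302 cluster on both scales fell, with miR-143-3p at -3.23 (adjusted p = 0.00219) and miR-302b-3p at -3.25 (adjusted p = 0.00413). miR-1a-3p, a muscle microRNA, fell by 6.80 ± 0.93 on the log2 scale (adjusted p = 1.5e-07), and miR-122-5p, the main liver microRNA, was at least 502-fold lower (258-fold in RPM), or 163-fold (165) from PGC male E11.5 alone. At least 19.98-fold, 12.5-fold and 7.11-fold lower were miR-669a-3p (12.6-fold in RPM, adjusted p = 0.0706 at equal totals), miR-206-3p (6.06-fold in RPM, 2.80-fold and 2.84-fold in RPM from PGC male E11.5 alone) and miR-370-5p (4.48-fold in RPM). miR-145a-3p (-5.10), miR-3099-3p (-4.65), miR-1197-3p (-4.61) and miR-666-5p (-4.53) completed the 10 largest decreases. Lists of other cell types moved with them: 6 of 10 erythroid (4 at equal totals), 2 of 2 endothelial, 3 of 4 muscle and 5 of 15 members of the miR-322 and miR-221 clusters (3 at equal totals) fell. At E11.5 endothelial microRNAs stood at 51442 RPM in PGC female and 27782 RPM in PGC male, near the 37105 and 30048 RPM of SC, and at E13.5 at 11230 and 6751 RPM. Dlk1-Dio3, miR-199a/214 and miR-143/145 stood at 0.917, 0.711 and 0.782 of the SC level in RPM in PGC female E11.5. In PGC male E11.5 they stood at 0.567, 0.702 and 0.641, and at E12.5 the means of both sexes were 0.348, 0.166 and 0.153. A fall within germ cells cannot be told apart here from a lower share of somatic cells in the fraction. The same limit holds for the rise of miR-290 and miR-182 cluster members in PGCs.

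On the deposited scale 40 microRNAs rose and 129 fell (median log2 -0.99), and at equal totals 38 rose and 110 fell (-0.41), with 29 and 104 called in the same direction on both scales. The deposited count of 169 became 22 without PGC female E11.5, 37 without PGC female E13.5, 80 without PGC male E13.5 and 80 with PGC libraries alone. At equal totals 148 became 93 without PGC female E11.5 and 96 without PGC male E13.5. Without both E11.5 female libraries 1 was called at equal totals, and 0 members of the Fx-mir, Dlk1-Dio3, miR-143/145 and miR-290 clusters passed on either scale. Without PGC female E11.5, 13 Fx-mir members (20 at equal totals), 4 Dlk1-Dio3 members (37), 1 miR-143/145 member (4) and 0 miR-290 cluster members passed, and all 26 Fx-mir members still had positive changes. In the remaining lists, on the deposited scale, members that rose and fell were 2 and 1 of 10 (gonadal), 1 and 1 of 4 (miR-34/449), 0 and 3 of 9 (Hox-cluster), 0 and 1 of 10 (miR-125/99/100) and 0 and 2 of 24 (Sfmbt2), with 0 in each other list. Camera with the preset correlation called, among others, Fx-mir higher (adjusted p = 9.8e-45) and Dlk1-Dio3 lower (1.5e-15), with adjusted p = 0.274 and 0.968 with an estimated correlation.

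In SC the same interval, when supporting cells of the ovary and testis arise, brought the rise of miR-202. miR-202-5p rose 85.8-fold (log2 6.42 ± 0.84, SE, adjusted p = 1.8e-08; 2 of 2 sexes; 66.7-fold at equal totals), from 226 RPM (female) and 136 RPM (male) at E11.5 to 8436 and 16334 RPM at E13.5. The let-7 family, which rises with differentiation, had 3 of 15 members rising, and 7 at equal totals (6 and 9 adjusted over the list alone), with let-7c-5p at 7.32-fold (log2 2.87 ± 0.79, SE, adjusted p = 0.00658; 2 of 2 sexes; 2.51 at equal totals). Families that were higher in PGCs rose as well: 24 of 26 Fx-mir members (19 at equal totals; 25 and 24 adjusted over the list alone) and 11 of 13 miR-290 cluster members (3 at equal totals; 12 and 11). By the naming rule, miR-741-3p was at least 111-fold higher (74.6-fold in RPM), miR-465c-5p 70.5-fold (46.4), miR-743b-3p 45.2-fold (29.9), miR-465b-5p 39.97-fold (27.1), miR-465a-5p 32.4-fold (21.2), miR-291a-5p 30.2-fold (20.04), miR-743a-3p 26.8-fold (17.6) and miR-290a-5p 24.9-fold (16.8), each against 0 in both E11.5 libraries. miR-881-3p (log2 7.79) and miR-871-3p (7.35), at 0 in SC male E11.5 and detected in SC female E11.5, rose by sizes that depend on the added 1. These families stood far below PGCs of the same day, where Fx-mir in SC was 8.73% (female) and 9.94% (male) of the PGC level and the miR-290 cluster was 3.74% and 5.06%.

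Falling in SC were miR-302b-3p of the miR-302 cluster (log2 -3.50; adjusted p = 0.0036; 2 of 3 members on both scales), miR-206-3p (-4.63; adjusted p = 0.00195) and miR-133a-3p (-5.04; adjusted p = 0.000888) of muscle. miR-122-5p (-5.61), miR-7b-5p (-5.22), miR-92b-3p (-3.20) and miR-375-3p (-2.53) passed on the deposited scale, with adjusted p = 0.259, 0.106, 0.0577 and 0.153 at equal totals. miR-140-3p of the gonadal list had a log2 change of 1.43 (adjusted p = 0.393), and 2 of 10 gonadal members passed. Dlk1-Dio3 had 0 of 82 members called (2 lower at equal totals), and 0 were called in each list not named here. By limma 43 rose and 13 fell (median -0.01), and at equal totals 34 and 7 (-0.34), with 29 and 4 shared. The 56 calls became 27 without SC male E11.5 and 37 without SC male E13.5. At equal totals the 41 became 5 without SC female E11.5, 5 without SC male E11.5, 19 without either E12.5 SC library, and 6 without SC male E13.5. It became 24 without both E11.5 female libraries and 51 without SC female E13.5, where 18 rose and 33 fell. Camera with the preset correlation called, among others, Fx-mir (adjusted p = 8.2e-35), the miR-290 cluster (1.5e-13) and let-7 (0.00344) higher, with adjusted p = 0.292, 0.968 and 0.968 with an estimated correlation.

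Whether the stage change differed between cell types was tested directly. It was more negative in PGCs for miR-669a-3p (log2 difference -10.39 ± 2.03, SE, adjusted p = 0.00182), miR-145a-3p (-5.00 ± 1.30; adjusted p = 0.0497), miR-1a-3p (-4.95 ± 1.32; adjusted p = 0.0497) and miR-291a-5p (-4.88 ± 1.29; adjusted p = 0.0497). These sizes depend on the added 1, since each of the 4 was at 0 in at least 1 of the libraries compared. With values of 0 raised to the floor of 5 reads 1 call was left, miR-669a-3p (-6.54), and the others had -3.75, -3.71 and -2.10 (adjusted p = 0.0822, 0.0822 and 0.322). miR-669a-3p was at 0 in both E13.5 PGC libraries and in SC male E11.5. miR-291a-5p rose in SC from 0 and in PGCs from detected values (log2 2.50, adjusted p = 0.0283, 0.130 at equal totals). Of the remaining microRNAs, miR-200a-3p (3.09; adjusted p = 0.123), miR-96-5p (2.67) and miR-9-5p (2.79) had the smallest p for a more positive change in PGCs and were not past the threshold. Among other lists, Dlk1-Dio3 changed more negatively in PGCs (camera with the preset correlation, adjusted p = 2.6e-08, median log2 difference -2.43) and the miR-200 family more positively (6.6e-09, 2.36), with adjusted p = 0.968 each with an estimated correlation. At equal totals limma called 0 (108 at an unadjusted p under 0.05), with adjusted p = 0.144, 0.144, 0.211 and 0.320 for the 4 microRNAs. On the deposited scale the count of 4 went to 0 without PGC male E11.5, either E12.5 PGC library, PGC male E13.5 or SC male E11.5. It went to 1 without PGC female E11.5, SC female E11.5 or either SC E12.5 library, to 2 without PGC female E13.5 and to 12 without SC female E13.5.

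Female and male PGCs were compared to find microRNAs that differ with sex. miR-758-3p of the Dlk1-Dio3 cluster was 7.20-fold higher in females (log2 2.85 ± 0.71, SE, adjusted p = 0.0462; 3 of 3 stages) and miR-669a-5p of the Sfmbt2 cluster was higher in 2 of 3 stages (4.62 ± 1.11; adjusted p = 0.0462), with 155 and 94.1 normalized counts in females at E11.5 and E13.5 and 0 in the other PGC libraries. The size for miR-669a-5p therefore depends on the added 1. Next by p, and not past the threshold, were miR-451a of red blood cells (2.47; adjusted p = 0.165), and, with higher values in males at 3 of 3 stages, miR-293-3p (-2.18 ± 0.69; adjusted p = 0.269) and miR-292a-5p (-1.58; adjusted p = 0.446), with miR-20b-5p at -1.52. Limma called 2 of 513 microRNAs (51 at an unadjusted p under 0.05) and 0 at equal totals (83), where miR-758-3p had an adjusted p of 0.268. The count was 0 without any 1 of the PGC libraries of E11.5 or E13.5 or of the SC libraries of E11.5 or E12.5, 1 without either E12.5 PGC library, and 0 with PGC libraries alone. Camera with the preset correlation placed the miR-290 cluster (adjusted p = 2.1e-14, median log2 -1.43), Fx-mir (3.8e-09, -0.85) and the miR-182 cluster (0.00455, -1.05) and miR-17/92 with its paralogues (0.00181, -0.22) lower, and Dlk1-Dio3 (3.4e-09, 1.08), miR-199a/214 (0.00423, 1.39) and miR-143/145 (0.0212, 1.52) higher in females. With an estimated correlation the adjusted p was 0.968 for each. Without PGC female E11.5, which stands apart from the other PGC libraries, the miR-290 cluster (adjusted p = 0.182, median -0.30) and Fx-mir (0.338, -0.17) were not called, and the other 5 lists were. Female and male shares of the miR-290 cluster were 12.8 and 14.3% at E12.5 and 9.78 and 11.9% at E13.5.

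In SC the sexes differed in 6 microRNAs on the deposited scale, each with a higher fitted mean in females. The muscle microRNA miR-206-3p was 15.2-fold higher (log2 3.92 ± 0.93, SE, adjusted p = 0.0144; 3 of 3 stages), miR-7b-5p was 13.5-fold higher (3.75 ± 0.81; adjusted p = 0.00586; 3 of 3 stages) and miR-669a-5p was higher in 2 of 3 stages (5.12 ± 1.11; adjusted p = 0.00586). The other calls, miR-122-5p, miR-219a-2-3p and miR-1298-5p, are named after their values were seen, with log2 changes of 3.96, 3.98 and 3.46. These sizes depend on the added 1, since miR-219a-2-3p was at 0 in SC male E11.5 and miR-122-5p and miR-1298-5p in SC male E13.5. So do the sizes of miR-7b-5p, at 0 in SC male E13.5, and miR-669a-5p, at 0 in SC male E11.5 and E13.5. At E11.5 miR-122-5p was higher in the male (1409 normalized counts in the female against 2102). Higher in males at 3 of 3 stages, but not past the threshold, were miR-202-3p (-2.05 ± 0.82; adjusted p = 0.358) and miR-455-3p (-1.30), with miR-465c-5p at -1.85 in 2 of 3 stages. miR-202-5p had 0.18 and miR-140-3p had -0.46 (adjusted p = 0.978 and 0.891). At equal totals limma called 0 (22 at an unadjusted p under 0.05, 42 on the deposited scale). The 6 calls became 0 without either E11.5 PGC library or either E11.5 SC library, 3 without any 1 of the other PGC libraries, and 1 or 2 without the female or male SC E13.5 library, and 0 with SC libraries alone. Camera with the preset correlation placed muscle microRNAs above the other microRNAs (adjusted p = 0.00108, median log2 1.96) and Fx-mir (0.000126, -0.07) and the miR-290 cluster (0.0482, 0.00) below them, where the median of all tested microRNAs was 0.52. At equal totals the adjusted p was 0.0123, 0.665 and 0.447, and with an estimated correlation 0.968 each.

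The difference between the sex effects of PGCs and SC was called by limma for 0 microRNAs on either scale (23 and 61 at an unadjusted p under 0.05). The smallest p belonged to miR-202-3p (log2 difference 3.11 ± 1.16, SE, adjusted p = 0.795), miR-770-3p (2.74) and miR-758-3p (2.39), and in the opposite direction to miR-122-5p (-4.14), miR-881-3p (-3.09) and miR-7b-5p (-3.07).

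At E11.5 the female PGC library held less of the miR-290 cluster than the male one. It had 326 normalized counts of miR-293-3p against 6254, 55.1 of miR-291a-5p against 1037, 37.5 of miR-290a-5p against 500.4, and 11.8 of miR-291b-5p against 248. It also had less of the Fx-mir member miR-881-3p (12.5 against 168). It had more miR-451a (1131 against 165), miR-206-3p (101 against 12.8) and miR-329-3p (1066 against 169.9). At equal totals the log2 ratios of these 3 went from 2.77, 2.89 and 2.64 to 1.497, 1.68 and 1.37, and that of miR-293-3p from -4.26 to -5.54. At equal totals 1 microRNA was at least 4-fold higher in the female and 21 in the male library, of 268, against 43 and 13 on the deposited scale. In PGCs at E12.5 miR-20a-5p (951 against 4171) was higher in males and miR-145a-5p (163 against 40.8) and miR-214-3p (195 against 65.6) in females, and at E13.5 miR-143-3p (4327 against 1183), miR-27a-3p (1538 against 389) and miR-199b-5p (248 against 59.0) were higher in females and miR-182-5p (9716 against 16739) in males. The 4-fold counts were then 0 and 6 of 136 (2 and 1 at equal totals) and 1 and 0 of 218 (0 and 0).

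In SC at E13.5 the male library held 4598 normalized counts of miR-202-3p against 191 in the female, a log2 ratio of -4.58, and 2338 of miR-455-3p against 276, 381 of miR-326-3p against 66.0 and 239 of miR-3102-3p against 39.1. The female library held 1239 of miR-122-5p, 387 of miR-1298-5p, 342 of miR-144-5p and 281 of miR-7b-5p, each at 0 in the male. At E12.5 miR-202-3p (147 against 388) and miR-202-5p (4415 against 7047) were higher in the male, while miR-206-3p (207 against 14.0) and miR-370-3p (8139 against 3220.2) were higher in females. At E11.5 miR-9-5p (6530 against 171), miR-219a-2-3p (337 against 0) and miR-669a-5p (443 against 0) were higher in the female library and miR-455-3p (216 against 350.3) in the male. In RPM these were 3026 against 245, 156 against 0, 205 against 0 and 100.1 against 504. The female to male 4-fold counts in SC were 101 and 0 of 331 at E11.5 (5 and 9 at equal totals, where the median log2 ratio went from 1.70 to 0.07), 1 and 0 of 282 at E12.5 on both scales and 14 and 14 of 319 at E13.5 (17 and 9). These are single pairs of libraries without a test.

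The change of the sex difference per embryonic day was called for 0 microRNAs in either cell type on either scale. In PGCs the smallest p values belonged to miR-291a-5p (2.12 log2 per day, female minus male), miR-290a-5p (2.03) and miR-295-3p (1.89), and to miR-184-3p (-2.31), miR-375-3p (-1.59) and miR-1198-5p (-1.27). In SC they belonged to miR-122-5p (5.43), miR-144-5p (3.83), miR-1298-5p (3.33), miR-470-5p (-2.40), miR-202-3p (-2.20) and miR-669a-3p (-4.48). Limma gave 1 and 6 microRNAs at an unadjusted p under 0.05 in PGCs and SC, and 7 and 9 at equal totals. Camera with the preset correlation called the miR-290 cluster (adjusted p = 3.9e-22) and Fx-mir (5.2e-11) as rising in female relative to male PGCs, with adjusted p = 0.486 and 0.968 with an estimated correlation. Without PGC female E11.5, neither was called (adjusted p = 0.522 and 0.466), and miR-375-3p had the opposite sign (0.72), and without PGC male E13.5 so had miR-184-3p (0.98) and miR-1198-5p (0.12). In SC, miR-669a-3p turned without SC female E11.5 (3.19) and miR-1298-5p without SC male E13.5 (-2.35).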

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

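The exchanges and regroupings of libraries were planned; the tests of somatic cells, labels, germ cells and scaling in this part were chosen after the result was seen. Each of the 24 lists was examined in the 6 libraries of each cell type for 1 library far from the rest, and 4 of 48 sets of libraries had one, where chance gives about 1 in 20. In PGC female E11.5, the miR-290 cluster stood at 2348 RPM and the miR-182 cluster at 6550 RPM, the latter below 30491 RPM in the next library. In SC male E13.5, miR-34/449 stood at 2965 RPM, above 847 in the next, and endothelial microRNAs at 16088 RPM, below 28958. The stage change differed between cell types, by the test of that difference on the deposited scale, for miR-669a-3p (log2 -10.39), miR-145a-3p (-5.00), miR-1a-3p (-4.95) and miR-291a-5p (-4.88); none of the 4 passed at equal totals, and with values of 0 raised to the floor 1 did, miR-669a-3p (-6.54).

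PGC female E11.5 was nearest to SC female E12.5 (Spearman rho 0.956 across microRNAs, which are not independent; 0.670 to 0.915 with other PGC libraries) and held 3.29% of the miR-290 cluster level of PGC male E11.5. Somatic cells in this fraction are a candidate explanation, as 5 lists that were higher in SC stood at a median of 0.917 of their level in SC female E11.5, though the labels give a PGC enrichment of 93 to 96%; in PGC male E11.5 the same lists stood at 0.567 to 0.925 of SC. An exchange of labels with a somatic library is argued against, since no SC library held more than 0.604% miR-290 cluster reads, against 7.13% or more in the other PGC libraries. A single wrong label cannot be told apart from a mixed fraction, because this library's miR-290 cluster share was 3.8 times that of the highest SC library of E11.5 and E12.5 and no second isolation exists to compare. A true difference between female and male PGCs at E11.5 is untested and open, since the design has 1 library of each.

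In the E13.5 SC libraries, Fx-mir stood at 8.73% (female) and 9.94% (male) and the miR-290 cluster at 3.74% and 5.06% of their PGC level, against 0.329 to 2.71% at E12.5. Germ cells carried into the somatic fraction may account for this, since the labels give a purity of over 90%, and would bring all their microRNAs in like shares. By the median of the members' log2 shares, Fx-mir exceeded the miR-290 cluster by 0.953 (mean of both sexes), which was 1.33 in the female (SD of members up to 0.83) and 0.58 in the male (up to 1.15), and by sums the miR-200 family was at 3.18% in the male and 11.04% in the female, after 10.1% and 11.2% at E12.5, so it did not follow the share of the miR-290 cluster. By sums the miR-182 cluster rose in both sexes, as the miR-290 cluster did. It went from 4.65% of its PGC level at E12.5 to 8.32% at E13.5 in the female, and from 2.70% to 4.12% in the male. Carried germ cells and an onset of these microRNAs in somatic cells cannot be told apart from these values, because the shares of both clusters lie under the 10% that the labels leave open and every SC library was made by the same separation.

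Most microRNAs were lower in PGCs on the deposited scale (median log2 -2.57). For those lower on that scale alone, the deposited scaling could be the source: in 20 simulated sets of reads without any difference between cell types, the deposited factors gave a median of 499.5 lower calls of 513, and equal totals 0. This outcome was set in advance by the depths and factors, which shift all microRNAs alike (median log2 -2.24). The sets also differed from the real data, with a median of 0 higher calls against 36 and more lower calls than the real 396. Fewer microRNAs among all small RNAs of PGCs would give the same median of -2.57, and both cannot be told apart because the features behind the factors are not given in the sources used here. For the 131 microRNAs that were lower at equal totals too, scaling as the whole cause cannot be excluded, since equal totals is itself a scaling. In simulated sets where 200 microRNAs were changed, it called 92.6% of the unchanged ones. By quantile normalization 102 microRNAs were lower, and by voom on the recovered reads 56. At equal totals 0 were lower without both E12.5 PGC libraries (17 called, all higher) or without both E13.5 SC libraries (7 called, all higher), fits with fewer libraries.

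Other splits of the libraries were counted for each comparison of at least 3 against 3. For PGC versus SC, exchanging cell types within pairs gave the real 432 calls in 1 of 32 exchanges, with 244 as the highest other, and at equal totals 200 against 133. The highest other on both scales exchanges the E11.5 female pair alone. This share is under 0.05 and the smallest the test can give, but it does not separate cell type from scaling that differs between the fractions. Simulated reads without a cell type difference gave a median of 499.5 lower calls under the deposited factors, an outcome set by the depths and factors. For sex the 10 splits are too few for a share under 0.05, with 2 calls in PGCs (highest other 1) and 6 in SC (highest other 5), and so are those for the slopes, with 0 calls in PGCs (highest other 315) and 0 in SC (highest other 1). The 315 calls came from PGC female E11.5 with both E12.5 PGC libraries against the rest, which points to a structure of the samples other than sex. On the deposited scale the median log2 level against the mean of the libraries was 0.67 in PGC female E11.5. It was -2.58 and -2.45 in PGC female and male E12.5, the lowest of all libraries, so differences in level go with this split. The split was not repeated at equal totals. For the difference between the sex effects, with 0 real calls (highest other 9), the 100 splits cannot test anything, as each gives at least 0.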

How the results depend on the processing

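Recomputed size factors, limma voom on the recovered reads, and values of 0 raised to the floor of 5 reads were chosen after seeing the data. So was the omission of both E12.5 PGC, both E13.5 SC or both E11.5 female libraries. List tests at equal totals, and list counts and list tests without doubted libraries, were also added then. The other alternatives in this paragraph were planned. The planned tests with count-based tools were left out, although whole reads could be taken back, and voom on these reads was run in their place. In the comparison of cell types, leaving out 1 library also took its partner out of the estimate, because the pair was a block. In the other comparisons, the partner of a library left out was assumed to vary like the other groups. For PGC versus SC the 432 calls became 200 at equal totals, 180 by quantile normalization (78 higher, 102 lower), 194 with recomputed factors (72 and 122) and 133 by voom (77 and 56), and ranged from 371 to 428 with 1 library left out; the other alternatives stayed within 1.5 times. The 2 calls for sex in PGCs became 0 with 0.5 added, without the filter, at equal totals, by quantile normalization, without the trend, with PGCs alone, with recomputed factors and by voom, 1 with 5 added, 1 with 0 raised to the floor, 1 without both E12.5 PGC libraries, and 0 to 2 with 1 library left out. The 6 calls for sex in SC became 0 with 0.5 added, without the filter, at equal totals, by quantile normalization, with SC alone, with recomputed factors and by voom, 1 without the trend, 3 without both E12.5 PGC libraries, 3 without both E13.5 SC libraries, and 0 to 5 with 1 library left out. For stage in PGCs the 169 calls became 80 with PGCs alone, where fewer libraries give the spread, and ranged from 22 to 174 with 1 left out; for stage in SC the 56 calls ranged from 27 to 69. The 4 calls for the difference in stage change became 0 with 0.5 added, without the filter, at equal totals, by quantile normalization, with recomputed factors, by voom and without both E12.5 PGC libraries, 1 without the trend, 1 with 0 raised to the floor, 2 with 5 added, 17 with a filter at a mean of 20, and 0 to 12 with 1 library left out. The difference in sex effects and both slopes had 0 calls under every alternative. The 4-fold counts between sexes, female and male, went at equal totals from 43 and 13 to 1 and 21 (PGC E11.5), from 0 and 6 to 2 and 1 (PGC E12.5), from 1 and 0 to 0 and 0 (PGC E13.5, also 0 with 5 added) and from 101 and 0 to 5 and 9 (SC E11.5). Of the 45 list calls, 0 held with an estimated correlation and 0 by fry.

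Among named microRNAs, 79 kept their direction and side of the threshold at equal totals and 14 lost the call, and with 1 library left out 997 results were the same, 114 weaker and 5 reversed. The 79 and the 997 include microRNAs named as not past the threshold, which had no call to lose. The 14 include every microRNA named as called for sex in PGCs, sex in SC and the difference in stage change. Reversed were miR-122-5p in the difference of sex effects by voom (0.16) and, among slopes that were not called, miR-375-3p without PGC female E11.5 (0.72, range from -3.90 with 1 library left out), miR-184-3p (0.98, from -5.61) and miR-1198-5p (0.12, from -2.67) without PGC male E13.5, miR-669a-3p without SC female E11.5 (3.19, from -12.15), miR-1298-5p without SC male E13.5 (-2.35, up to 9.02), and miR-144-5p (-1.06) and miR-1298-5p (-2.08) without both E13.5 SC libraries. Where no reason is given, the cause was not tested. Depth limits the E12.5 PGC libraries most, where 5 reads are 27.1 to 29.98 RPM.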

Other observations

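The microRNAs in this part were chosen after their values were seen, from single libraries and without tests. SC male E13.5 held several microRNAs at levels unlike the other SC libraries. The miR-30 family took 134497 RPM there, against 33824 to 59572 RPM in the other SC libraries, with miR-30a-5p at 49618 RPM. miR-34c-5p stood at 2603 RPM (290 to 775 in the others), miR-140-3p at 4978 RPM (985 to 1505), miR-455-3p at 1383 RPM (100.1 to 504) and miR-202-3p at 2719 RPM (5.09 to 280.3). Its Hox-cluster miR-10a-5p stood at 6955 RPM, against 47647 to 76903 RPM in the other SC libraries.

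MicroRNAs known from other organs differed in level between libraries. The liver microRNA miR-122-5p stood at 4280 and 2015 RPM in PGC female and male E11.5, 653 and 3023 RPM in SC female and male E11.5 and 842 RPM in SC female E13.5, and at 0 in SC male E13.5 and both E13.5 PGC libraries. The neural miR-9-5p stood at 3026 RPM in SC female E11.5, against 117 to 245 RPM in the other SC libraries, and at 981 to 3430 RPM in PGCs.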
